A study of Gallus gallus with 7 samples.

How the data were processed

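Reduced representation bisulfite sequencing (RRBS) reads DNA methylation in CpG-rich fragments, because bisulfite turns unmethylated cytosines, and not methylated ones, into bases read as thymine. It was applied to microglia, the resident macrophages of the brain, which per the labels had been sorted by flow cytometry from the anterior hypothalamus of chicks on day 10 after hatch. Per the labels, each library came from a pool of 10 to 12 chicks and from 15 to 30 ng of DNA, and the conditioned chicks had been kept at 39 °C for 24 hours on day 3. The comparison has 4 non-conditioned libraries, numbered 1 to 4, and 3 conditioned libraries, numbered 1-2, 3 and 4. The labels do not say how the conditioned library numbered 1-2 was made, and it was treated as 1 library.

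The tools named in the submitters' processing notes are Trimmomatic, Bismark 0.22.3, Bowtie and HOMER, and the genome build named there is galGal5. The deposited site table gives percent methylation for each cytosine position in each library, with no scaling between libraries. Its values are percentages of methylated calls, and the number of calls behind them is not given, so the depth is unknown and no value below carries an interval for it. The site table holds 1048575 positions on chromosomes 1, 10, 11, 12 and 13 and on chromosome 14 up to position 4886681, so library values of other chromosomes were not analysed here. With its header the table has exactly as many lines as a spreadsheet can hold, so it appears incomplete, and counts of positions per library refer to this part only. Positions 1 bp apart are the cytosines of both strands of a CpG, and 83.5% of positions have such a partner in the table.

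The deposited segment table covers 53008 short segments on 779 chromosomes and scaffolds, 745 of which are unplaced scaffolds. For each segment, per the file headers, it gives the mean percent methylation of each group, a p-value of a Mann-Whitney U test, a p-value of a Kolmogorov-Smirnov test, a q-value and the count of CpG positions. The difference column deposited by the authors is non-conditioned minus conditioned, in percentage points; here every difference is conditioned minus non-conditioned. The tool that made the segments is not named in the sources used here. Segment means recomputed from positions measured in all 7 libraries matched both deposited group means within 0.01 percentage points in 11570 of the 11570 segments inside the site table, with the first coordinate of the segment table counted from 0. Coordinates are given counted from 1, on galGal5. In the deposited values, the q-value equals the Kolmogorov-Smirnov p-value times about 427083 (range 425000 to 428926, over 931 segments with a q-value under 1). Over 579 segments, the deposited Mann-Whitney p-value had a Spearman correlation of 0.982 with a rank-sum test that takes every position of every library as an observation, and of 0.670 with a rank test on library means. For the deposited Kolmogorov-Smirnov p-value the correlations were 0.975 with the pooled test and 0.503 with the test on library means. The smallest deposited p-values are 4.02e-14 and 1.21e-16, whereas exact tests of both kinds on 4 and 3 libraries cannot give a p under 0.0571. The settings of the authors' tests are not stated, so this is read from the values.

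Library means were compared by an exact permutation test of the absolute difference between group means, two-sided, over all 35 arrangements of the libraries; its smallest p is 0.0286. The common positions are the 513180 measured in all 7 libraries. Regions were tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend) on log2((fraction + 0.05)/(1 - fraction + 0.05)) of the mean methylation of a region in each library, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The offset of 0.05 shrinks log2 differences of regions near 0 or 100%. Tested regions were 500-bp tiles with at least 3 common positions and the authors' segments inside the site table, both with a mean between 2% and 98%. Because the segments were found on these libraries, their retest is not independent evidence. Other computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The limma step was tested on simulated data made from the real regions, with 200 regions changed. For tiles it recovered 12% of changes of 1 log2 unit and 63% of changes of 2 log2 units, with 1 call outside the changed tiles. For segments it recovered 18% and 67%, with 3 calls outside. The simulated noise was drawn independently for each region and library, with no shift of a whole library. These counts therefore hold for such data only.

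Level classes sort each cytosine by the mean methylation of its partner on the opposite strand over all 7 libraries, so that a position's own noise does not place it in a class. The level classes, the classes of tiles by number of positions, the correlation of neighbouring positions, level-matched centring, the tests of each strand alone, Benjamini-Hochberg adjustment of the deposited p-values and the pooled rank-sum test were chosen after seeing the data. The tests of library means, tiles and segments, the rules below and the remaining alternatives were fixed before the data were examined. Named segments are those with a deposited q-value under 0.05 whose library means do not overlap between the groups, at most 12 in each direction by size of difference. Named tiles are those past the limma threshold or, if none passes, the 5 with the smallest p in each direction. Any other region is said to have been chosen after its values were seen.

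Alternatives were another offset (0.01), untransformed fractions, centring of each library on its median or within 20 bins of the mean level, at least 5 positions per region, no filter on the mean, an exact permutation test per region, positions measured in at least 2 libraries of each group, tiles of 1000 and 200 bp, each strand alone, a term for the replicate number, stricter thresholds on the deposited segments, and each library left out. Limma was also run on all 35 splits of the libraries into 4 and 3. Genes were not named and promoters and fixed gene lists were not tested, because the gene table at hand is of the assembly GRCg7b and coordinates were not converted between builds.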

Results

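The 7 RRBS libraries describe CpG methylation in hypothalamic microglia of chicks that had or had not met a day of heat a week earlier, before any immune challenge. The question is whether early heat conditioning leaves a difference in microglial DNA methylation. Values were given at 689894, 694825, 665694 and 652465 positions in non-conditioned libraries 1 to 4, and at 724260, 862443 and 834475 positions in conditioned libraries 1-2, 3 and 4. All 7 libraries shared 513180 positions, 48.9% of a site table that appears incomplete, and the read depth behind each value is unknown. Most of these positions were nearly unmethylated: 67.0% had a mean under 10%, 26.6% lay between 10% and 80%, and 6.42% lay above 80%. Across positions, which are not independent replicates, Pearson's r between pairs of libraries ran from 0.810 for non-conditioned 3 with non-conditioned 4 to 0.898 for conditioned 3 with conditioned 4. Pairs between the groups had 0.825 to 0.857, above every pair of non-conditioned libraries (0.810 to 0.819). Pairs of conditioned libraries had 0.854 to 0.898. Similarity between libraries therefore did not simply follow the groups.

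Mean CpG methylation over the common positions was 18.8% ± 0.404 (SD, n = 4) in non-conditioned and 17.7% ± 2.00 (SD, n = 3) in conditioned microglia. The conditioned libraries fell on both sides of the non-conditioned range, which ran from 18.2% to 19.0%. Conditioned library 1-2 stood above it at 19.9%, while conditioned libraries 3 and 4 stood below it at 15.97% and 17.2%. The difference of -1.09 percentage points did not pass (exact permutation p = 0.371) and was smaller than the spread of the conditioned libraries. It was -0.240 points without conditioned library 3 (exact p = 0.867) and -2.19 points without conditioned library 1-2, where the exact p of 0.0667 is the smallest that 4 against 2 libraries allow.

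Conditioned libraries 3 and 4 both lay below the non-conditioned libraries at low levels and parted at intermediate ones. Conditioned library 3 was 2.48 points below the non-conditioned mean at partners under 2% and 4.20 points below it at partners of 50% to 80%. Conditioned library 4 was 2.06 points below it at partners under 2% and 0.306 points below it, within the non-conditioned range, at partners of 50% to 80%. At cytosines whose partner on the opposite strand averaged under 2%, methylation was 4.79% ± 0.165 (SD, n = 4) in non-conditioned libraries, 2.31% in conditioned 3, 2.73% in conditioned 4 and 4.82% in conditioned 1-2. At partners of 2% to 5% the non-conditioned mean was 6.49% and the conditioned mean 4.82%. At partners of 20% to 50%, conditioned library 1-2 reached 36.7% against a non-conditioned mean of 31.2% ± 0.98 (SD, n = 4). At partners of 80% or more the groups had 76.3% ± 0.591 (SD, n = 4) and 75.7% ± 0.752 (SD, n = 3). None of the 7 level classes passed, with a lowest exact permutation p of 0.0857 and a lowest Benjamini-Hochberg adjusted exact p of 0.30.

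**Figure D1:**
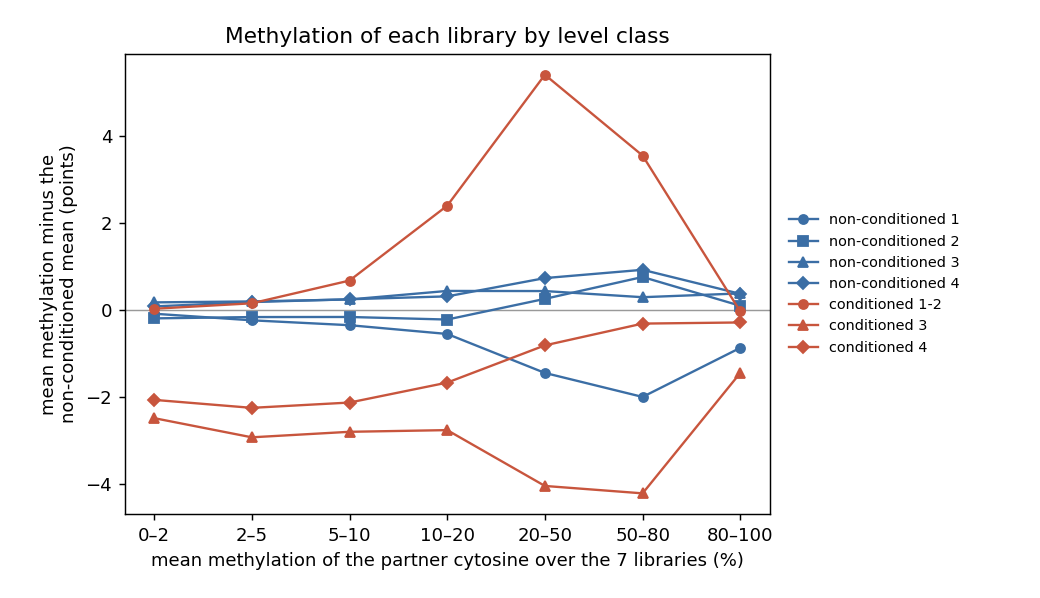
Mean methylation of each library minus the non-conditioned mean, in percentage points, against the mean level of the partner cytosine in percent; each line is a library, blue for non-conditioned and red for conditioned. Below 10%, conditioned libraries 3 and 4 lie about 2 to 3 points under the non-conditioned libraries, and conditioned library 1-2 lies above them between 10% and 80%.

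Conditioned library 1-2 had the highest and conditioned library 3 the lowest mean on each of the 6 chromosomes with library values. Chromosome 1 had the lowest methylation, with 15.4% ± 0.349 (SD, n = 4) in non-conditioned and 14.2% ± 1.69 (SD, n = 3) in conditioned microglia. Chromosome 12 had the highest, with 23.2% ± 0.479 (SD, n = 4) and 22.4% ± 2.14 (SD, n = 3). The difference ran from -1.24 points on chromosome 1 to -0.834 points on chromosome 12. On chromosomes 10, 11, 13 and the first part of chromosome 14 it was -0.902, -0.969, -1.08 and -1.24 points. The Benjamini-Hochberg adjusted exact permutation p was 0.486 on each.

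In the authors' own comparison, conditioned microglia had lower methylation in most segments that passed. Of 53008 segments, 362 had a deposited q-value under 0.05, of which 329 were lower and 33 higher after conditioning. These were mostly small differences at low levels: the median was 5.23% in non-conditioned and 1.59% in conditioned microglia, and 322 of the 362 had a non-conditioned mean under 10%. Differences of 10 points or more went both ways, in 15 segments higher and 16 lower. A segment under 10% cannot be lower by that much, and 294 of the 329 lower segments had a non-conditioned mean under 10%. Of the 12 that differed by 20 points or more, 8 were higher.

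The passing segments were spread over the genome. Chromosome 2 had 38, chromosome 1 had 33 and chromosome 3 had 31, of 4316, 5234 and 3853 segments. All 18 passing segments of the Z chromosome, of 2279 there, were lower after conditioning. Of all Z segments, passing or not, 82.8% were lower. Z was not alone in this: all passing segments were also lower on chromosomes 14 (15 segments), 13 (9), 9 (8), 19 (7) and 10 (6), among others. Chromosomes 2, 1 and 3 had 5, 4 and 2 higher ones. Unplaced scaffolds had 14 lower and 1 higher. Outside the chromosomes with library values, the 3 largest differences toward higher methylation, chosen after their values were seen, were at chromosome 25, 1349529 to 1349596 (10 positions, deposited means 10.4% and 67.4%, q = 8.23e-05), chromosome 23, 5267952 to 5268018 (12 positions, 20.8% and 51.9%, q = 0.0386) and chromosome 26, 615347 to 615423 (19 positions, 8.55% and 38.7%, q = 8.41e-06). The smallest q on an assembled chromosome, also chosen after it was seen, belonged to chromosome 3, 8135924 to 8135968, with 7.33% and 1.89% over 20 positions (q = 6.59e-10). The direction was not limited to passing segments, since 77.6% of all 53008 were lower in conditioned microglia, with a median difference of -1.88 points. Both kinds of deposited p-value tracked tests that take every position of every library as an observation, and such tests do not measure the spread between libraries.

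**Figure D2:**
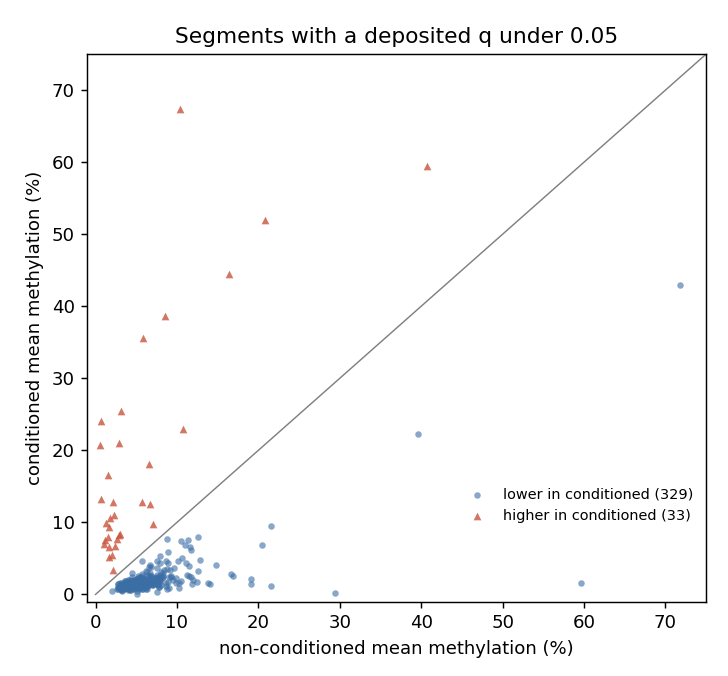
Deposited mean methylation of the 362 segments with a q-value under 0.05, in percent, non-conditioned on the horizontal and conditioned on the vertical axis; each point is a segment and the line marks equal means. The 329 lower segments crowd below 10% on the horizontal axis, where the distance below the line is bounded by 0, and the 33 higher segments lie above the line.

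Library values could be computed for 78 of the passing segments, 72 lower and 6 higher in conditioned microglia. In 56 of them (52 lower and 4 higher), every conditioned library lay on the same side of every non-conditioned library. That is 71.8%, against 19.2% of all 11570 segments with library values. Chance gives 5.71% for 4 against 3 in regions not chosen on their difference; these segments were found on the same libraries, so their share is a description only. Among the 72 lower segments, conditioned library 1-2 was nearer to the non-conditioned mean than to the mean of conditioned 3 and 4 in 20.

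The 4 higher segments among the 56 had non-conditioned means of 0.63% to 5.81% and conditioned means of 11.1% to 35.5%. The segment at chromosome 1, 106084792 to 106084859, had 5.81% ± 7.26 (SD, n = 4) in non-conditioned and 35.5% ± 9.69 (SD, n = 3) in conditioned microglia over 19 positions. The segment at chromosome 11, 906760 to 906805, had 1.48% ± 2.39 (SD, n = 4) and 16.6% ± 6.08 (SD, n = 3). The segment at chromosome 1, 185465516 to 185465582, had 0.63% ± 0.72 (SD, n = 4) and 13.2% ± 8.15 (SD, n = 3). At chromosome 12, 11759824 to 11759862, the means were 2.32% ± 3.00 (SD, n = 4) and 11.1% ± 5.69 (SD, n = 3).

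The 12 lower segments with the largest differences had conditioned means of 0.132% to 6.17%. The largest gap, at chromosome 1, 42795657 to 42795726, came with wide spread: 45.5%, 90.8%, 11.3% and 91.0% in the non-conditioned libraries and 0, 1.03% and 3.69% in the conditioned ones. The segment at chromosome 1, 36471370 to 36471421, had 29.4% ± 24.0 (SD, n = 4) and 0.132% ± 0.229 (SD, n = 3). These 2 segments had positions of 1 strand only. The segment at chromosome 14, 761248 to 761361, had 21.6% ± 15.9 (SD, n = 4) and 1.16% ± 0.318 (SD, n = 3). The segment with the smallest limma p of the 16 was at chromosome 1, 84962455 to 84962500, with 19.1% ± 6.37 (SD, n = 4) and 1.47% ± 1.27 (SD, n = 3) over 22 positions. Its difference was -27.3 points on one strand and -7.97 points on the other. The segment at chromosome 12, 8731775 to 8731837, had 11.5% ± 3.05 (SD, n = 4) and 2.62% ± 2.28 (SD, n = 3) over 26 positions, and differed by -9.81 and -7.93 points on the strands. The other 7 lower segments differed by between -12.6 and -5.53 points.

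**Figure D3:**
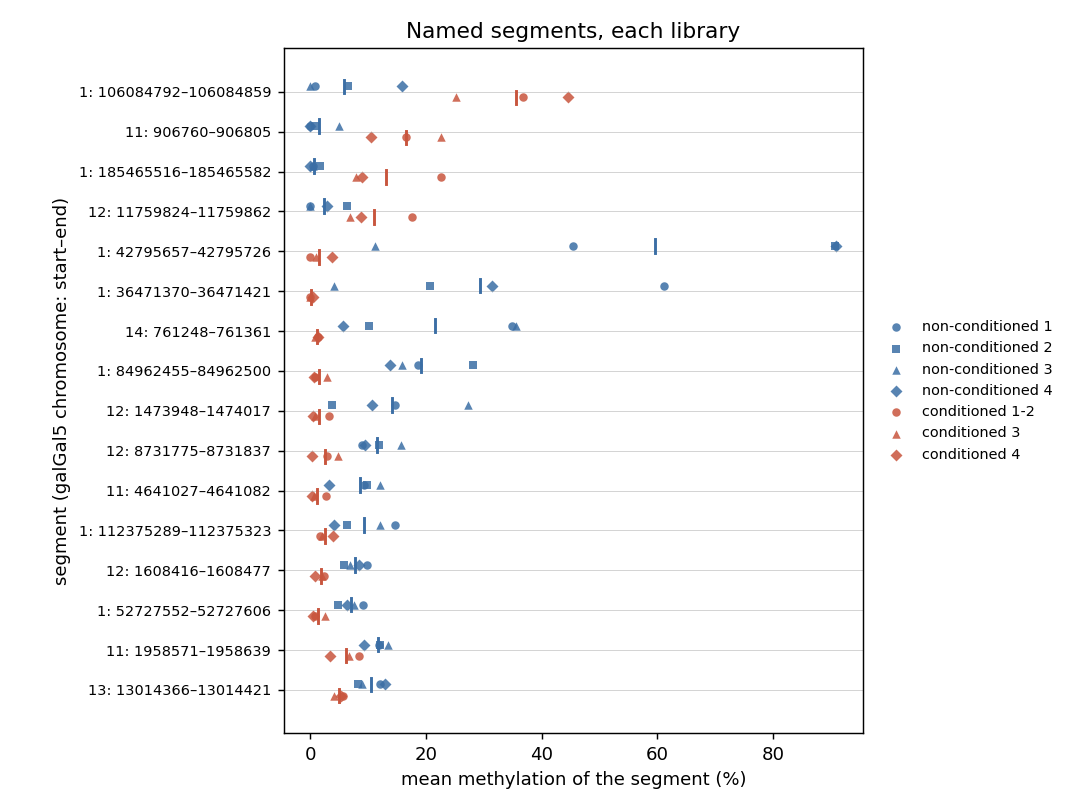
Mean methylation in percent of each library in the 16 named segments, with their galGal5 coordinates on the vertical axis; points are libraries, blue for non-conditioned and red for conditioned, and short vertical bars are group means. The groups do not overlap in any of the 16, by the rule that chose them, and the non-conditioned libraries spread widest at chromosome 1, 42795657 to 42795726.

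When libraries were the replicates, 1 of 10276 segments passed. It lies at chromosome 1, 67300055 to 67300086, was named because it alone passed, and had 15.7% ± 1.64 (SD, n = 4) in non-conditioned libraries and was listed at 0 in all 3 conditioned libraries over its 10 positions (limma adjusted p = 0.0408). Its deposited q-value was 1, and it did not pass with any library left out; without conditioned library 3 a different segment passed (chromosome 12, 9204250 to 9204336). None of the 16 named segments passed, with limma adjusted p from 0.253 to 0.26; at chromosome 1, 84962455 to 84962500, the log2 ratio difference was -2.15 (SE 0.32, limma adjusted p = 0.253). At an unadjusted p under 0.05 limma gave 1900 segments, 240 higher and 1660 lower, a direction that turned to 1577 higher and 158 lower with each library centred on its median, and to 865 and 360 with level-matched centring. That unadjusted count was 2851 without conditioned library 1-2, 1154 without conditioned 3 (435 higher and 719 lower) and 996 without conditioned 4. The median log2 difference of all retested segments was -0.36, and 0.07 with median centring. Median centring adds the same amount to the log2 difference of every segment, so the turn it gave follows from its construction.

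Fixed 500-bp tiles, laid out without regard to the groups, gave no passing region: limma called 0 of 18784 tiles, with a lowest adjusted p of 0.0644. At an unadjusted p under 0.05 it gave 1129 tiles (6.01% of those tested), 212 higher and 917 lower in conditioned microglia. Under level-matched centring, whose construction favours a balance of tiles, 442 were higher and 430 lower. With each library centred on its median, 255 were higher and 1204 lower. That centring moved the median log2 difference of tiles only from -0.1261 to -0.1172, so it could hardly change the balance. The exact permutation test per tile called 740 without adjustment and 0 with it (lowest adjusted p 0.725). Its p cannot go under 0.0286 in any tile, so that 0 says little about passing. The unadjusted limma count was 2399 without conditioned library 1-2 (166 higher and 2233 lower), 857 without conditioned 3 (354 higher and 503 lower) and 683 without conditioned 4. Without non-conditioned library 1, and likewise without non-conditioned library 2, 1 tile passed.

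The tiles with the smallest limma p, none of which passed, lay at methylated as well as nearly unmethylated sites. The tile at chromosome 1, 106249001 to 106249500, was listed at 100% in all 4 non-conditioned libraries and had 72.7% ± 6.30 (SD, n = 3) in conditioned ones over 4 positions of 1 strand (limma adjusted p = 0.0644). The tile at chromosome 10, 20013501 to 20014000, had 69.6% ± 6.72 (SD, n = 4) in non-conditioned libraries and 35%, 40% and 25% in the conditioned ones over 5 positions. The tile at chromosome 10, 14345501 to 14346000, had 7.31% ± 1.57 (SD, n = 4) and 0.377% ± 0.444 (SD, n = 3) over 14 positions, and its groups did not overlap on either strand. Among higher tiles, chromosome 1, 157053501 to 157054000, had 70.03% ± 3.58 (SD, n = 4) and 89.0% ± 2.71 (SD, n = 3) over 4 positions. The tile at chromosome 11, 17628001 to 17628500, had 3.75% ± 4.79 (SD, n = 4) and 30.0% ± 8.0 (SD, n = 3) over 5 positions of 1 strand. The limma adjusted p of the 5 higher tiles ran from 0.618 to 0.784.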

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

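The tests on the level of conditioned libraries 3 and 4, level-matched centring, the strand tests, the splits of the retested segments and of unadjusted counts, and the rank-sum test over pooled positions were chosen after the results were seen. Among 41 sets of non-conditioned values examined for a library far from the rest, 1 stood out, where chance gives about 2.05. It was the tile at chromosome 1, 109674001 to 109674500, where non-conditioned library 2 had 16.7% against 10.0%, 10.7% and 10.0% (gap over range 0.893), and the conditioned libraries had 45.7%, 26.8% and 44.2%.

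Over the common positions, conditioned libraries 3 and 4 had lower methylation than every non-conditioned library, and conditioned library 1-2 did not. Over all positions each library measured, conditioned library 4 (22.92%) lay above non-conditioned libraries 1 (22.29%) and 4 (22.87%). Different sets of measured positions are argued against as the whole cause, since the gap was 2.19 points over positions measured in all 7 libraries, with a non-conditioned SD of 0.404. Less complete bisulfite conversion in the other libraries could add apparent methylation mostly at unmethylated cytosines; at partners of 80% or more it would allow both libraries together a gap of 0.611 points, and the gap was 0.860 points, an excess within the non-conditioned SD of 0.591. Taken singly, conditioned library 3 had gaps of 4.03, 4.20 and 1.44 points at partners of 20% to 50%, 50% to 80% and 80% or more. Its gaps below 20% allow 2.20, 1.32 and 0.757 points, and the excess was over the non-conditioned SD in 3 of the 3 classes. That goes against conversion as the whole cause there but does not exclude it, since 1 library carries all 3 classes. Single libraries can stray as far: at 20% to 50%, conditioned library 1-2 had 36.7% against a non-conditioned mean of 31.2%. Conditioned library 4 (0.807, 0.306 and 0.281 points) exceeded its allowance in 0 of the 3, and conversion stays open for it. Heat conditioning stays open too: conditioned library 1-2 lay 1.11 points above the non-conditioned mean, but 1 library of unexplained numbering excludes nothing. Coverage also set conditioned libraries 3 and 4 apart. They had values at 82.2% and 79.6% of positions, against 62.2% to 69.1% in the others. Of the common positions they had 43.0% and 40.7% at 0 (27.8% to 37.4% in the others). At 100% they had 2.50% and 2.79% (3.59% to 5.18% in the others). Whether these traits share a cause with the lower level was not tested.

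Most differences between the groups pointed to lower methylation after conditioning, and a shift of whole libraries could give this. With each library centred within bins of the mean level, 49.3% of tiles at an unadjusted p under 0.05 were lower. The share was 81.2% without it and 82.5% with each library centred on its median. Median centring moved the median log2 difference of tiles only from -0.1261 to -0.1172. It could therefore hardly change the share, and the 82.5% does not show that the direction outlasts a shift. Centring within bins removes the mean group difference of each bin, which favours an even split. A shift and heat conditioning therefore cannot be told apart. The 0 tiles that passed say nothing about chance, since all 35 of 35 splits give at least 0 (highest other split 4), and 2 of 35 splits gave at least the 1 retested segment (highest other 1), which does not exclude chance. At an unadjusted p, 8 of 35 splits gave as many tiles as the 1129 of the real grouping (highest other 1895), but with that median centring 1 of 35 did, the real one (1459, highest other 1369); that is the smallest share 35 splits allow, but the count is among 7 examined and was chosen after the results were seen, so chance is not taken as excluded. The real grouping also gave the most segments at an unadjusted p (1 of 35 splits; 1900, highest other 1178), and with median centring (1 of 35; 1735, highest other 944), but the segments were chosen on this grouping. With the rank-sum test over pooled positions, 11 of 35 splits gave as many tiles as the 336 of the real grouping, and the 4 splits that join conditioned libraries 3 and 4 with a non-conditioned library gave 710 to 865, which points to a structure of the samples in which those 2 libraries are low together.

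The largest segment differences could come from a few molecules of 1 strand read many times. In 0 of the 16 named segments did the groups stay apart on both strands taken singly, but a strand holds only 1 to 13 of a segment's positions, so that count decides little. In 14 of the 14 segments measured on both strands the difference had the same direction on both. Its median was 5.50 points (lowest 2.405) on the strand with the smaller difference and 10.1 points on the other. In 4 segments the larger strand difference was over 3 times the smaller. The shared direction goes against a single strand as the whole cause there. However, the segments were chosen on both strands together, and most of all segments were lower, so it does not exclude that explanation. For the 2 segments with positions of 1 strand (chromosome 1, 42795657 to 42795726 and 36471370 to 36471421), this explanation and heat conditioning cannot be told apart.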

How the results depend on the processing

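Level-matched centring, single strands and Benjamini-Hochberg adjustment of the deposited p-values were chosen after the data were seen. Mean methylation over positions shared between libraries stayed lower in conditioned libraries under every alternative run, from -2.19 to -0.240 points with a library left out. It passed under none, but the exact p cannot go under 0.0667 without a conditioned library, 0.1 without a non-conditioned one or 0.0833 with the block, so those say nothing about passing. Over all positions each library measured, which differ between libraries, a lower conditioned level was not seen. Those means were 22.3%, 23.6%, 23.4% and 22.9% in non-conditioned libraries 1 to 4. They were 24.9%, 21.6% and 22.9% in conditioned libraries 1-2, 3 and 4. The passing deposited segments numbered 31 with a difference of at least 10 points, which removes small differences by construction. They numbered 15769 with Benjamini-Hochberg adjustment of the Kolmogorov-Smirnov p over the 53008 deposited segments alone. The deposited q-value is that p times about 427083, so the adjustment is milder in method and in the number of tests. Those p-values do not measure the spread between libraries. Passing tiles numbered 3 with positions measured in at least 2 libraries of each group (2 higher and 1 lower in conditioned), 1 at 1000 bp (lower) and 1 at 200 bp (higher). With a library left out 0 to 1 passed (1 each without non-conditioned 1 and 2, each higher). The 1000-bp tile contains the named tile at chromosome 1, 106249001 to 106249500, and has the same log2 ratio difference of -3.107. Its limma adjusted p was 0.0439 among 14745 tiles, against 0.0644 for the named tile among 18784. Why these tiles passed was not tested further. The retest of segments gave 0 with untransformed fractions, median centring, positions measured in at least 2 libraries of each group, single strands or level-matched centring, and 0 to 1 with a library left out; the cause was not tested. It also gave 0 with the exact permutation test (lowest adjusted p 0.265), whose p cannot go under 0.0286 in any region. The share of segments lower at an unadjusted p under 0.05 reversed with median centring, to 9.11%, and with level-matched centring, to 29.4%. Median centring adds the same amount to the log2 difference of every segment, which moved their median from -0.36 to 0.07. Segments that were only a little lower then count as higher, so that reversal follows from the centring. Level-matched centring removes the mean group difference of each bin, and the cause of the turn it gave was not tested. For tiles, level-matched centring gave an even 49.3%, a balance its construction favours. With the replicate block 0 tiles and 0 segments passed, and 963 tiles and 1537 segments did at an unadjusted p. Same-numbered libraries, with conditioned 1-2 taken to match non-conditioned 1 and 2, deviated together by correlations of -0.0757 to 0.0437. Not every library correlated best with its own number. The named regions kept their direction in all 285 refits of segments and 166 of tiles. Segments were chosen for groups that do not overlap and tiles for a small p, in these same data. Most of these refits could therefore hardly turn the direction, and the count adds no support. Autosomes only could not be run as an alternative, since the library values are of autosomes alone; overlap with passing tiles gave no value, since none passed; promoters and gene lists were not run for want of an annotation of the build. Unknown depth limits how firmly any single region can be read.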

Other observations

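The tests by number of positions and the neighbour correlations in this part were chosen after the data were seen. Tiles of 500 bp with more common positions had lower methylation in every library. Only positions measured in all 7 libraries are counted, so the number mixes CpG density with coverage. Non-conditioned libraries had a mean of 55.7% ± 0.909 (SD, n = 4) over 4592 tiles of 3 to 5 positions, 46.7% ± 0.947 over 5840 tiles of 6 to 15, 29.5% ± 0.598 over 3068 tiles of 16 to 30, and 12.3% ± 0.322 over 5615 tiles of 31 or more. Conditioned libraries had 55.0% ± 1.03, 45.9% ± 2.40, 28.5% ± 2.75 and 11.1% ± 1.98 (SD, n = 3) in the same classes. The smallest difference, -0.747 points, was in the tiles with the fewest common positions and the largest, -1.17 points, in those with the most. None of the 4 classes passed (exact permutation p from 0.314 to 0.571, Benjamini-Hochberg adjusted exact p 0.571 in each).

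Within a library, neighbouring cytosines of the same strand had correlated deviations. Reads had 75 cycles, so close neighbours can be called on the same reads. Shared sampling and shared methylation were not told apart. The deviation of a library from the mean of all 7 had a correlation of 0.352 between neighbours 1 to 10 bp apart, 0.273 at 11 to 30 bp, 0.167 at 31 to 60 bp, 0.0384 at 61 to 150 bp and 0.0116 beyond that, up to 1000 bp, over 4415 to 159477 pairs on one strand. On the other strand the correlations were 0.356, 0.273, 0.169, 0.049 and 0.0191. The passing deposited segments had a median length of 62 bp and a median of 20 positions.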
